A study of Mus musculus with 6 samples.

How the data were processed

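Gene expression was measured in 6 neurosphere cultures of mouse cortical precursors, 3 transfected with a nonsense control oligonucleotide and 3 with a 2'-O-methyl antisense oligonucleotide against miR-335. Per the labels' protocols, the cells came from the dorsal telencephalon of C57BL/6 fetuses at embryonic day 12.5 and were kept in serum-free medium with bFGF (20 ng/ml), EGF (20 ng/ml) and LIF (0.15 ng/ml). The labels give the duration of the transfection as 24 without a unit. Per the labels, 2 µg of total RNA was made into biotin-labelled cRNA and hybridised for 18 h to CodeLink mouse arrays, which are read in a single colour.

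The values deposited by the authors are linear intensities divided by each array's median; the median scaling is per the labels, and the file headers name CodeLink Expression Analysis 4.1.0.29054. That the local background was subtracted was read from the scanner values, not from the labels. Scanner output was used for 2 of the 6 arrays, replicate 1 of each group. On these arrays all 35976 and 36032 values present in both sources equalled the normalized intensity of the scanner output within 0.0001, row by row, so scale and direction are settled there. The medians of the gene probes lay between 0.991 and 0.996 on all 6 arrays. On the 2 arrays with scanner output, masked spots and spots with the software's flags I or C are empty in the deposited intensities. Slide and scan batches could not be tested, because scanner headers were used for a single array per group.

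Of the 36227 rows, 34967 are gene probes and the rest are control spots, which were left out of the tests. Gene names came from the platform's annotation table, updated through the RefSeq gene table of assembly GRCm38.p6. It names 1 symbol for 21615 gene probes, several for 681 and none for 12671, and no gene was named from a probe with several. The gene identifiers of 21487 of the single-symbol probes were found in the RefSeq table, which changed 0 symbols. The annotation's accession equalled the scanner output's for 83.3% of the annotated probes. A probe was called above background on an array when its intensity exceeded the negative control spots' median by 3 scaled median absolute deviations. That limit lay between 0.492 and 0.692, and between 59.9% and 67.3% of the gene probes exceeded it. For arrays, the number of arrays limits the precision, here 3 per group.

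Intensities below the 5th percentile of all positive values, 0.163, were raised to it and log2 was taken. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 34847 probes with at least 2 values per group, and the threshold was an adjusted p of 0.05. Fold changes are anti-miR-335 minus control on the log2 scale; means and SDs are of the linear intensities. Where every array of a group was below the background limit, the fold is given as a bound, taken against the higher of the dim probe's own value and the lowest value above background on each array. The 26 gene lists, with 509 entries of which 463 were measured, were tested with limma's camera at a preset correlation of 0.01. That test used 1 probe per gene, the brightest on average, over 17688 genes with values on all 6 arrays, with adjustment over the 26 lists. Estimated correlations and fry, limma's rotation test, were run beside it. Simulated data with known changes were used to test the scripts. Of 50 probes changed at each size among 34847, the simulated comparison of anti-miR-335 with control recovered 22% at 1.5-fold, 70% at 2-fold, 88% at 3-fold and 92% at 4-fold, with 4 false calls among 140. The changed probes were drawn only from those with a mean at or above the array median. Noise was normal and independent, and no simulated array deviated as a whole. These shares are therefore not the power of the comparison on the real arrays. In the simulated gene lists, a list shifted by 0.5 was called by camera (adjusted p = 3.2e-17) and 0 other lists were, over 17688 genes. The simulated genes varied independently of each other, so this run cannot show how often lists of correlated genes are called falsely.

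The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes up to 12 probes per direction past the threshold, with a single symbol, group values that do not overlap and a mean at or above the array median in at least 1 group, largest fold first. Where fewer than 10 qualify in a direction, it fills up to 10 with the smallest unadjusted p, given as values that did not pass. It always takes Mest, Jag1, Elavl2, Sox4 and Tnc where measured, and from each list up to 4 members that passed or otherwise the 2 of smallest p; clone names are passed over in the first parts. Mest, the host gene of the microRNA, shares its probe with another symbol and is not reported. The alternatives were quantile normalization, other floors, a filter on dim probes, blocks by replicate number, other limma settings, and leaving out each array or numbered pair. A planned comparison of genes with and without a miR-335 seed match in the 3' UTR was not run, because no UTR sequence was used here. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.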

Results

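Neurospheres are floating clusters of neural precursor cells. They were grown from embryonic mouse cortex and transfected either with an antisense oligonucleotide against the microRNA miR-335, which blocks it by pairing, or with a nonsense oligonucleotide as control. RNA levels were read on 6 single-colour arrays, 3 per group. The submitters describe the 3 replicates of each group as independent without saying what was repeated, so p-values measure the spread between these 6 samples. Intensities are in units of each array's median and are given as mean ± SD with n = 3 per group. MicroRNA levels were not analysed here, so the block itself has no check. The spike-in control spots had a median of 3.49 on control replicate 1, the lowest of the 6 arrays, against 3.89 to 5.19 on the others.

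The question was which mRNAs differ when miR-335 is blocked. Padi2, which encodes a peptidylarginine deiminase, had an intensity of 29.5 ± 3.40 in the anti-miR-335 arrays and 14.6 ± 1.33 in the controls, a log2 difference of 1.01 ± 0.12 (SE). Ppp2r2b, a regulatory subunit of protein phosphatase 2A, lay at 29.4 ± 1.43 against 15.4 ± 1.79. The neurotrophic factor gene Cntf lay at 36.4 ± 5.45 against 19.2 ± 1.22, and the growth factor receptor gene Pdgfra at 15.9 ± 2.39 against 7.95 ± 1.46. Among lower values, the cell cycle regulator Ccnd2 lay at 14.8 ± 1.93 in the anti-miR-335 arrays against 22.8 ± 1.66, and the microglial receptor gene Trem2 at 3.27 ± 0.127 against 4.85 ± 0.221. Group values that do not overlap were a condition for naming these genes, and none of them passed the test. Padi2 and Ppp2r2b had the smallest adjusted p by limma, 0.109.

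By limma, 0 of 34847 probes passed an adjusted p of 0.05, while 3162 had an unadjusted p under 0.05 against 1742 expected by chance, 1710 of them higher and 1452 lower in the anti-miR-335 arrays. Of the 9 other splits of the 6 arrays into 3 and 3, 8 gave fewer (808 to 2555), and 1, which exchanges the replicate 1 arrays between the groups, gave 5090. Group values did not overlap for 14.9% of the probes, where chance gives 10%. This count rests on control replicate 1: without it 1100 probes passed, 786 higher and 314 lower, Padi2 (adjusted p = 0.00618) and Ppp2r2b (adjusted p = 0.00421) among them. Leaving out the whole replicate 1 pair gave 1571, and array weights gave 474, though these changed all 6 arrays, from 0.37 for control replicate 1 to 2.25 for control replicate 2.

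The remaining genes of smallest p were spread over several functions, and none passed the test. Higher values in the anti-miR-335 arrays were found for the adhesion molecule gene Vcam1 (log2 difference 0.76 ± 0.12 SE), the glutamate transporter gene Slc1a1 (0.93 ± 0.15) and the water channel gene Aqp4 (0.69 ± 0.11). Prkcq, a protein kinase C gene, differed by 0.80 ± 0.13, Nme1, a nucleoside diphosphate kinase gene, by 0.71 ± 0.12, and Chic2 by 0.77 ± 0.13, although a second Chic2 probe gave 0.12 ± 0.17. Lower values were found for Akna (-0.63 ± 0.12), the chemokine gene Ccl4 (-0.51 ± 0.10), the chromatin remodeller gene Chd3 (-0.51 ± 0.11) and Ranbp1 of the Ran transport cycle (-0.47 ± 0.10). Arhgef38 differed by -0.58 ± 0.12 and Septin4 by -0.67 ± 0.14. Mgp, the matrix Gla protein gene, was not above background on any anti-miR-335 array and was at least 1.75-fold higher in the controls (adjusted p = 0.333 by limma). Tra2a, a splicing factor gene, differed by -0.88 ± 0.15 on a probe at 42.2 ± 7.21 in the controls, but by 0.24 ± 0.16 on a second probe of like brightness.

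**Figure D1:**
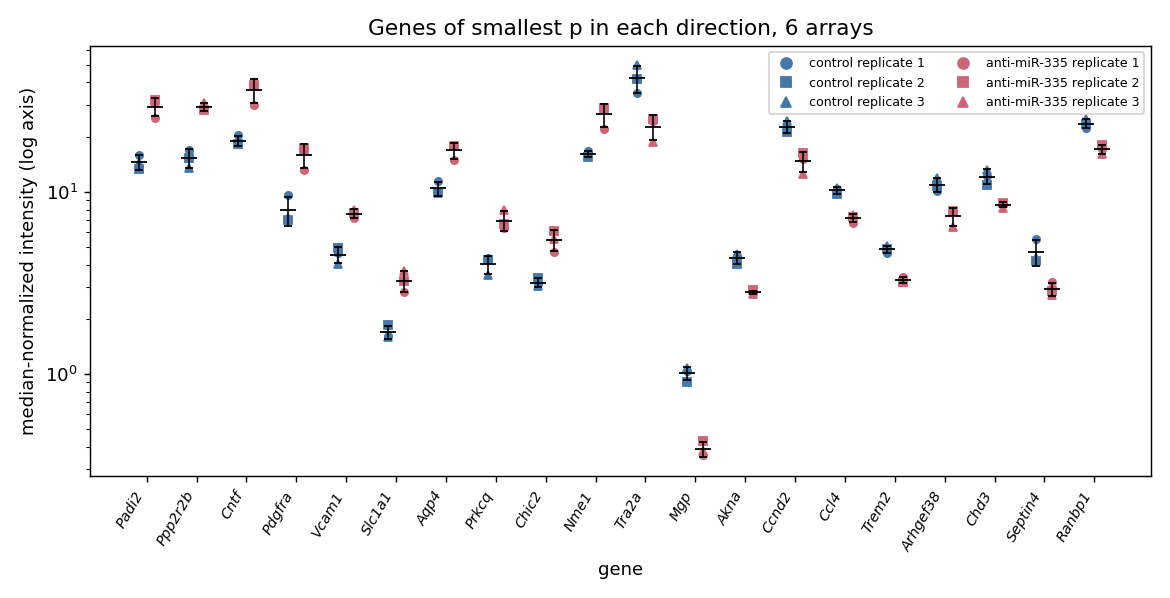
Median-normalized intensity (log axis) of 10 genes in each direction, those of smallest p among the probes that met the naming rule. The 3 control arrays are in blue and the 3 anti-miR-335 arrays in red. Black bars are mean ± SD. Group values that do not overlap were part of that rule. None of the 20 genes passed the adjusted p of 0.05 by limma (smallest 0.109).

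Genes reported elsewhere as miR-335 targets were measured for 15 of 17 entries, and none passed. The extracellular matrix gene Tnc lay at 83.2 ± 8.12 against 73.2 ± 5.63 in the controls, and the Notch ligand gene Jag1 at 1.61 ± 0.108 against 1.52 ± 0.130. Sox4, a transcription factor gene, lay at 1.08 ± 0.350 against 0.916 ± 0.296 on its brighter probe, close to background. Elavl2, a neuronal RNA-binding protein gene, was not above background on any control array. The smallest p among the targets belonged to the retinoblastoma gene Rb1 (log2 difference 0.53 ± 0.19 SE) and the kinase gene Rock1 (-0.38 ± 0.15), which lie in opposite directions. The 15 measured members had a median log2 difference of 0.14; camera used the 13 with values on all 6 arrays, leaving out Rock1 and Mertk, and gave an adjusted p of 0.537.

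Of the 26 gene lists, 3 were higher in the anti-miR-335 arrays by camera, and for each the call was lost with an estimated correlation. The immediate early genes, which cells switch on within minutes of a stimulus, had a median log2 difference of 0.69 over 19 measured members, all positive (camera adjusted p = 6.6e-10; adjusted p = 0.574 with an estimated correlation). None of the 19 passed over all probes, and 10 rose when adjusted over the list alone. Fos lay at 147 ± 40.2 against 69.6 ± 12.7 in the controls, and Jun at 56.0 ± 3.98 against 30.2 ± 8.31. Control replicate 1 stood with the anti-miR-335 arrays in this list: its members lay 0.71 (median log2) above their mean in control replicates 2 and 3, where the anti-miR-335 arrays lay 0.93 above it.

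Cholesterol synthesis genes were measured for 13 of 17 entries, with a median log2 difference of 0.45 (camera adjusted p = 5.5e-06; adjusted p = 0.574 with an estimated correlation). Of the 13, 11 were positive, 0 passed over all probes and 6 rose when adjusted over the list alone. Fdps, farnesyl diphosphate synthase, lay at 23.9 ± 5.96 against 13.1 ± 1.69, and Cyp51, the lanosterol demethylase, at 9.09 ± 2.53 against 4.93 ± 0.395; a second Cyp51 probe gave a log2 difference of 0.10 ± 0.25. The list's mean, relative to the controls, was 0.012, 0.012 and -0.024 on the control arrays and 0.197, 0.754 and 0.638 on anti-miR-335 replicates 1, 2 and 3. By the median over members, control replicate 1 lay 0.18 above control replicates 2 and 3, and the anti-miR-335 arrays 0.43 above them.

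Neuronal genes had a median log2 difference of 0.19 over 23 members, 19 of them positive (camera adjusted p = 0.0112; adjusted p = 0.574 with an estimated correlation). None passed over all probes and 2 rose when adjusted over the list alone: Dcx, doublecortin of migrating neurons, lay at 4.99 ± 1.18 against 2.42 ± 0.144, and Crmp1, a growth cone protein gene, at 4.51 ± 0.959 against 2.64 ± 0.180. Without control replicate 1 the list's adjusted p was 0.182, and without the replicate 2 pair 0.211.

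**Figure D2:**
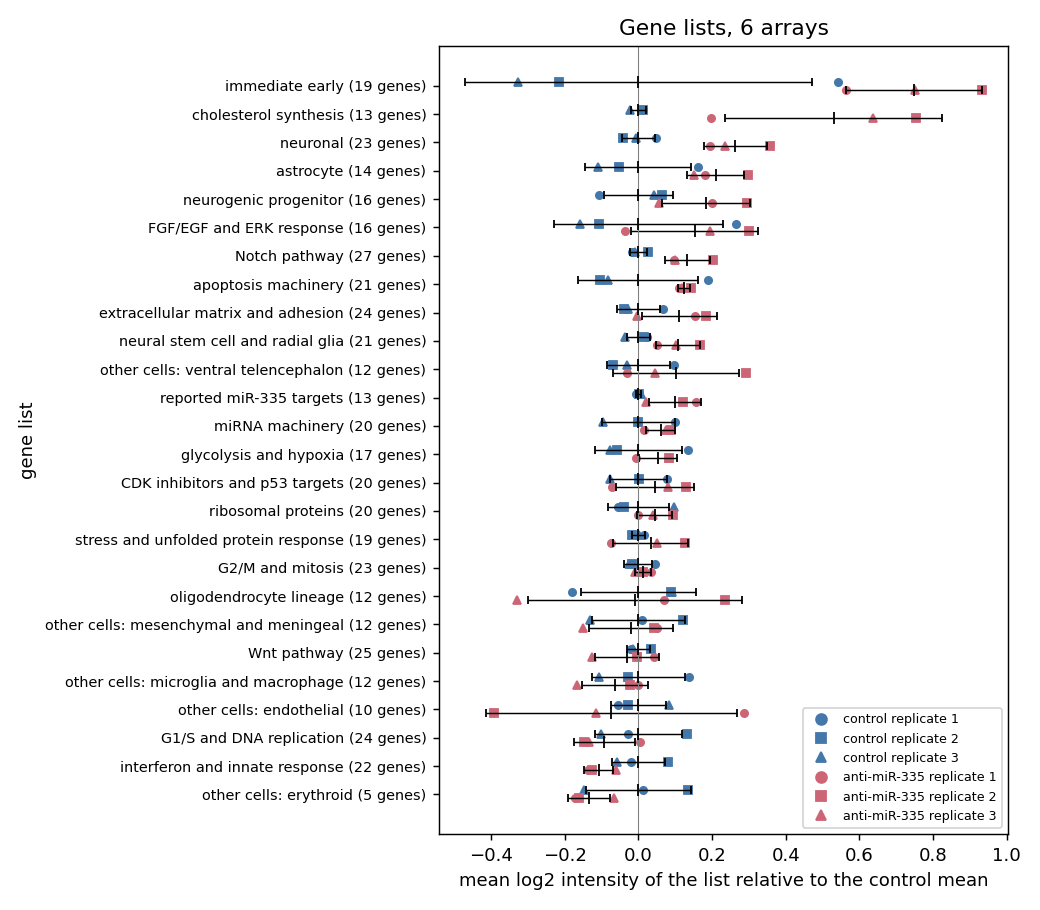
Mean log2 intensity of each list's genes relative to their control mean, per array (points) and as group mean ± SD over 3 arrays (black), controls in blue and anti-miR-335 in red. The immediate early list averaged 0.749 in the anti-miR-335 arrays, with control replicate 1 at 0.541, and the cholesterol synthesis list averaged 0.530.

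The other 23 lists did not pass, with camera adjusted p between 0.120 and 0.973, and 0 of their members passed over all probes. Adjusted over the list alone, 2 members rose in each of the astrocyte, neurogenic progenitor, Notch and CDK inhibitor lists and 1 in each of the neural stem cell, oligodendrocyte and stress lists, while 1 fell in each of the CDK inhibitor and G1/S lists. These counts overlap: Hes5 counts in the neural stem cell and Notch lists, and Dll3 in the neurogenic progenitor and Notch lists. Btg2 of the CDK inhibitor list is also an immediate early member. Among glial lists, astrocyte genes had a median of 0.15 over 14 members (adjusted p = 0.120), the gap junction gene Gja1 differing by 1.13 ± 0.24 (log2, SE). Oligodendrocyte lineage genes had a median of -0.16 (adjusted p = 0.871), Sox10 lying at 3.29 ± 0.139 against 2.55 ± 0.301; Olig1 was at 1.93 on control replicate 1 and 1.61 on anti-miR-335 replicate 3, against 18.6 to 26.8 on the other arrays. Neural stem cell genes had a median of 0.07 over 21 members (adjusted p = 0.427), with Hes5, a Notch effector, at 4.44 ± 0.0680 against 2.60 ± 0.434 and Msi2 at 20.4 ± 2.01 against 15.8 ± 3.31. Neurogenic progenitor genes had a median of 0.16 (adjusted p = 0.120), with Rnd2 at 17.8 ± 2.95 against 11.7 ± 0.482. The Notch pathway had a median of 0.11 over 27 members (adjusted p = 0.184), with the ligand gene Dll3 at 26.3 ± 2.41 against 19.0 ± 2.00.

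Proliferation and survival lists had medians near 0. G1/S and DNA replication genes (adjusted p = 0.537) had a median of 0.05 but a mean of -0.09, the helicase gene Mcm4 lying at 9.76 ± 0.258 against 8.30 ± 0.340. G2/M genes had a median of 0.02 with a camera direction of lower (adjusted p = 0.537); Cenpf lay at 1.07 ± 0.114 against 1.45 ± 0.260, and Cenpe was not above background on any array. CDK inhibitors and p53 targets had a median of 0.10 over 21 members (adjusted p = 0.537 over the 20 with values on all arrays), with Btg2 at 25.3 ± 2.10 against 16.5 ± 4.44 and Plk3 at 8.49 ± 0.455 against 11.2 ± 1.01. Apoptosis genes had a median of 0.13 (adjusted p = 0.537), Diablo and Cycs differing by 0.28 ± 0.10 and 0.27 ± 0.11 (log2, SE).

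Signalling and metabolic lists were as follows. Wnt genes had a median of 0 (adjusted p = 0.537), with Wnt5a at -0.49 ± 0.18 and Axin1 at 0.34 ± 0.13 (log2, SE). FGF/EGF response genes had a median of 0.07 (adjusted p = 0.537), with Fgfr3 at 0.62 ± 0.27 and Phlda1, above background on 1 of 3 control arrays, at 0.75 ± 0.32. Interferon genes had a median of -0.07 (adjusted p = 0.236), with Isg15 at 0.41 ± 0.17 and Mx1, above background on 2 control arrays and 1 anti-miR-335 array, at -0.56 ± 0.27. MicroRNA machinery genes had a median of 0.07 (adjusted p = 0.537), with Ddx5 at 0.30 ± 0.13 and Xpo5 at 0.28 ± 0.13. Stress response genes had a median of 0.04 with a camera direction of lower (adjusted p = 0.973), Dnajb1 lying at 0.54 ± 0.11 and Sdf2l1 at -0.46 ± 0.17. Glycolysis and hypoxia genes had a median of 0.09 (adjusted p = 0.579), with Vegfa at 0.47 ± 0.18 and Adm at 0.21 ± 0.12. Extracellular matrix genes had a median of 0.10 (adjusted p = 0.537), Mmp14 lying at 0.35 ± 0.11 and Lamc1 at -0.33 ± 0.12. Ribosomal protein genes had a median of -0.01 and a mean of 0.04 (adjusted p = 0.537), with Rps7 at 0.33 ± 0.12 and Rplp1 at 1.29 ± 0.36, the latter above background on 1 of 3 control arrays. Tested for change in either direction with fry, the Notch and extracellular matrix lists had an adjusted p of 0.0333. That test asks whether members differ at all, not whether they differ more than other genes. For a shift in 1 direction, the adjusted p was 0.184 and 0.537 by camera and 0.217 and 0.63 by fry.

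Markers of other cells that could be present did not pass either. Microglia and macrophage markers had a median of -0.01 (adjusted p = 0.537), with 2 of 12 above background on at least 3 arrays; Ptprc was not above background on any array and Lyz2 on 1 control array. Endothelial markers had a median of -0.04 (adjusted p = 0.601), with 5 of 10 above background on at least 3 arrays, but not Flt1 and Pecam1, the 2 of smallest p. Mesenchymal markers, 3 of 12 above background, had a median of 0.15 but a mean of -0.02 (adjusted p = 0.661), Pdgfrb being above background on 1 control and 2 anti-miR-335 arrays and Rgs5 on 1 control and 0 anti-miR-335 arrays. Ventral telencephalon markers, 7 of 12 above background, had a median of 0.02 (adjusted p = 0.916), with Gad1 at 15.2 ± 2.69 against 11.8 ± 4.14 and Dlx2, above background on 2 of 3 control arrays, at 1.12 ± 0.0166 against 0.851 ± 0.322. Erythroid markers had a median of -0.18 over 5 members, 1 above background (adjusted p = 0.537); Epor was above background on 2 control arrays and at least 1.07-fold higher there, and Klf1 was not above background.

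**Figure D3:**
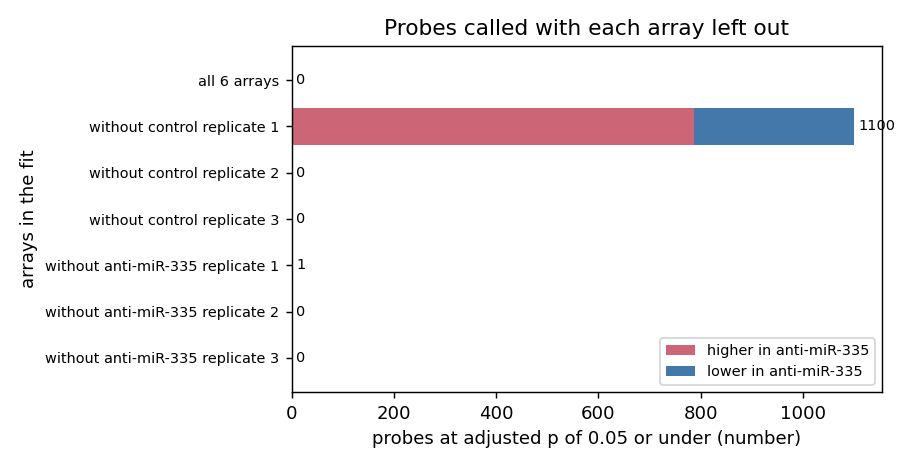
Number of probes at an adjusted p of 0.05 or under with all 6 arrays and with each array left out, split into probes higher (red) and lower (blue) in anti-miR-335. The count is 0 with all arrays, 1100 without control replicate 1, 1 without anti-miR-335 replicate 1, and 0 without each of the other 4.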

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

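All alternatives here were fixed before the data were examined. The count of 0 probes stayed at 0 with a replicate block, replicate 1 as a batch term, both other floors, dim probes left out and no intensity trend. It also stayed at 0 for the 19987 probes with good flags on both replicate 1 arrays, flags of the other arrays not being used. The count was 1 after quantile normalization, 3 with a robust trend and 474 with array weights. Of these 474, 386 were among the 1100 called without control replicate 1. Leaving out arrays or pairs gave 0 to 1571 probes: 1 without anti-miR-335 replicate 1, 1100 without control replicate 1, 1571 without the replicate 1 pair, and 0 in the other 6 cases. The deviations of same-numbered arrays from their group means correlated at -0.25, 0.07 and -0.29 over 16624 probes. Each replicate 1 array lay toward the other group, which by itself makes the -0.25 negative. Control replicate 1 also weighs on the control mean behind the other values, so these correlations cannot decide on pairing. The main fit left the arrays unpaired, as fixed in advance. The 3 called lists became 0 with an estimated correlation and 0 with fry. Leaving out arrays gave 2 to 5 lists, 5 without anti-miR-335 replicate 3 and 2 without control replicate 1, anti-miR-335 replicate 2 or the replicate 2 pair. With an estimated correlation the adjusted p was 0.574 for each called list, the test's preset correlation of 0.01 giving way to 0.438 (immediate early), 0.404 (cholesterol synthesis) and 0.028 (neuronal); by fry it was 0.273, 0.217 and 0.217. Leaving out arrays gave adjusted p from 4.4e-15 to 9.8e-06 for immediate early, 2.8e-09 to 0.00865 for cholesterol synthesis and 0.0041 to 0.211 for neuronal genes, the last over 0.05 in 4 of 9 cases (0.182 without control replicate 1, 0.061 without anti-miR-335 replicate 2, 0.0912 without the replicate 1 pair, 0.211 without the replicate 2 pair). Neuronal genes also missed the threshold at the 20th percentile floor (0.0563) and with the mean of all probes (0.11). The cause was not tested. Among 72 named probes, 37 passed without control replicate 1, all in their direction. Most of these probes were named for a small p over arrays that this fit shares, so the 37 are no separate support. Sox4 and Elavl2, at or near background, turned sign: the brighter Sox4 probe was at -0.082 with array weights and from -0.296 to 0.536 over the leave-out cases. The dim Sox4 probe was at -0.019 after quantile normalization, -0.901 with no floor and -0.115 with array weights, and from -0.669 to 0.567 over the leave-out cases; Elavl2 ranged from -0.212 to 0.69. On the scanner intensities of the replicate 1 pair, 33 of the 72 log2 differences lay within 1 moderated SD of the value over all arrays. This sets 1 pair, which holds control replicate 1, against all 6 arrays. It therefore cannot separate the processing from the choice of arrays. The seed site comparison and its alternatives were not run.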

Other observations

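The further lists of immediate early and lipid genes were chosen after the called lists were seen, but before the values of their genes were. The tests on control replicate 1, on the control arrays' spread, on scaling, on other splits and on the probes low on 2 arrays were chosen only after the result was seen.

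Lipid genes beyond the fixed list were also mostly higher in the anti-miR-335 arrays. Of 11 measured genes that the sterol-responsive factor SREBP regulates, 9 were positive, with a median log2 difference of 0.35 (camera adjusted p = 0.000612 over the 2 further lists; adjusted p = 0.117 with an estimated correlation of 0.108). Scd2, a fatty acid desaturase gene, had intensities of 60.3, 48.8 and 50.9 on the control arrays and 68.5, 76.5 and 79.0 on the anti-miR-335 arrays; Scd1, a close relative, differed by -0.63 ± 0.17 (log2, SE). As a hypothesis, lipid synthesis genes may be higher together when miR-335 is blocked; because the call needed both correlations and met 1, 0.000612 leaves it open. A second list of 18 immediate early genes had a median of 0.01 (camera adjusted p = 0.617), so a rise across immediate early genes in general was not found, although Fosl2, Bhlhe40 and Klf10 had unadjusted p under 0.05.

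Gene annotation terms were tested as well, without a list fixed in advance. Of 496 terms with 10 to 300 genes, 0 passed by camera (54 had an unadjusted p under 0.05), and the smallest adjusted p was 0.148.

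Control replicate 1 lay close to the anti-miR-335 arrays. On an axis over all 34204 complete probes, control replicates 2 and 3 defined 0 and anti-miR-335 replicates 2 and 3 defined 1. Control replicate 1 lay at 0.83 (0.71 to 0.95 over 4 ways of assigning the arrays) and anti-miR-335 replicate 1 at 0.48 (0.43 to 0.52). The position depended on the arrays chosen. With anti-miR-335 replicate 2 placed in place of replicate 1, control replicate 1 lay at 1.44 (0.92 to 1.88) and the placed array at 1.55. With anti-miR-335 replicate 3 placed, they lay at 1.33 (0.9 to 1.64) and 1.56. A shift shared by the replicate 1 pair alone would make their deviations correlate above 0, and they correlated at -0.25. Each array of the pair lay toward the other group, which by itself makes this correlation negative. The -0.25 therefore cannot decide whether a shared shift was present as well. The spike-in medians ran in a similar order. They were 3.49 on control replicate 1, then 3.89, 4.18 and 4.47 on anti-miR-335 replicates 3, 2 and 1. Control replicates 3 and 2 had 4.38 and 5.19. Whether a technical difference between arrays gives these positions was not tested, so it stays open beside the labels. A wrong label of control replicate 1 alone, or an effect shared by control replicates 2 and 3, may give the 0.83. Exchanged labels of the replicate 1 pair stay open at 0.48. These tests and their rules were rewritten after results were seen: an earlier rule would have argued against an exchange, and earlier positions of 0.80 and 0.55 came from probes selected to separate the other 4 arrays. Axes that do not leave out control replicate 1 were too unstable to read, with positions from -20.48 to 8.15.

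Immediate early genes differed among controls as well as between groups. Control replicate 1 lay 0.71 above control replicates 2 and 3 (median log2), where the anti-miR-335 arrays lay 0.93 above them, and Zfp36, chosen after its values were seen, had 79.0 there against 21.0 and 19.3. Scaling between arrays is argued against by a median log2 difference of 0.62 after quantile normalization. Anti-miR-335 replicate 1 lay only 0.06 (median log2) above control replicate 1. Variation among control arrays met an earlier rule. A further condition, loss of the call in a leave-out case, was added after the result was seen and was not met. This variation stays open: the 0.71 lies toward the anti-miR-335 arrays and narrows the group difference. The list passed in all 9 leave-out cases, but at a preset correlation, and the label of control replicate 1 is itself in doubt. An effect of the antisense oligonucleotide stays open beside variation among control arrays.

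A set of 28 probes, singled out after their values were seen, was over 2-fold lower on control replicate 1 and anti-miR-335 replicate 3 than on each of the other 4 arrays, where the next pair of arrays had 8. Bcan, a brain proteoglycan gene, had 0.645 and 0.516 there against 4.19 to 6.10. The likeness of the 2 arrays was wider than these probes. Over 16624 probes their deviations from their group means correlated at 0.36, the highest of any control array with any anti-miR-335 array. Their spike-in medians, 3.49 on control replicate 1 and 3.89 on anti-miR-335 replicate 3, were the lowest of the 6 arrays. A technical cause was not tested. Lower mRNA is argued against for the 5 genes with a second probe above background (Cbs, Apba3, Pou3f3, Pxn and Zfp319), since 0 of these probes was lower on both arrays. For the other 23 genes, without a second probe above background, it stays open. Fewer oligodendrocyte lineage cells, for Olig1 and Olig2, are argued against by 0 of 5 other lineage markers being lower in both; the treatment cannot set this pair apart, since it holds an array of each group.

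With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 0 probes, so all 10 gave as many, and the highest other, which puts control replicate 1 with anti-miR-335 replicates 2 and 3, called 52; that split points to a structure of the arrays, but control replicate 1 had already been seen to lie nearest those arrays, so it is no separate evidence on labels. For gene lists the real split called 3. Of the 10 splits, 2 called as many, the real one included, the highest other being 3.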
